A study of Mus musculus with 26 samples.

How the data were processed

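RNA was amplified and sequenced from 26 samples, per the labels' protocols. Antibody injections, 100 µg of each antibody given 2 times a week, began 2 weeks before E-A14 cells were placed in the mammary fat pad of FVB/N mice. Tumours were digested with collagenase and DNase, and live cells without CD90, CD105 or CD45 were sorted by Her2 and EpCAM. The cDNA was made from 0.1 to 1.0 ng of total RNA with the SMARTer v4 kit and amplified by 10, 12 or 14 cycles of PCR. Libraries were made with Nextera XT and sequenced on a HiSeq 1000 as single reads of 50 bases. The labels do not say which library had which number of cycles, and the kit marks neither strand nor single molecules. Each sample was assigned to its group by its title, which gives 6 libraries for each of the 4 tumour groups and 2 for the cultured line. The labels do not say whether the 2 culture replicates were grown separately, so their spread may be technical. P-values against them use a spread shared by all groups.

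The authors deposited a table of raw read counts per gene, made with the aligner STAR (version not given in the sources used here) on the mouse build mm9, per the submitters' processing notes. The counting program, the annotation release and the strand setting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The authors deposited a second table on a log2-like scale, per the submitters' processing notes made with DESeq2 1.22.2, whose exact transformation is not stated. Its values have a shared floor and rise by about 1 for each doubling of high counts, and they were used only in an alternative EMT score. The count table has 47730 features, of which 47729 are Ensembl mouse genes and 1 is the rat Neu transgene. Of the Ensembl genes, 47224 were matched by identifier to a symbol of the GENCODE M21 annotation. Because that annotation is on another build than mm9, no coordinates are given.

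All tests used the counts as deposited. Normalization was by edgeR 4.0.16 (TMM) under R 4.3.3, and features were kept by its filter on counts per group, which left 16637. A quasi-likelihood model with 1 coefficient per group was fitted to all 26 libraries, so that the groups shared an estimate of spread. From it 7 comparisons were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. These were EpCAM-negative against EpCAM-positive cells in each treatment, the difference of these 2 changes, control against depleted in each fraction, and each fraction against the cultures. For the last 2, the mean of the control and depleted coefficients was used. Each gene's log2 fold change was taken from the fit and its standard error was derived from the test statistic. No replicate block was used.

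The EMT score of a library was the mean log2 CPM (prior count 2) of the mesenchymal minus that of the epithelial list, since the formula behind the score named in the design is not given in the sources used here. Groups of scores were compared with exact two-sided permutation tests, and the difference of the EpCAM contrasts by permuting the treatment over the 12 differences of libraries that share a number. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. An adjusted p with the correlation estimated per list stands beside each list that passed without a block. Of 42 lists, 40 had at least 5 tested members. The lists cover epithelial and mesenchymal identity, matrix, antigen presentation, interferon and inflammatory genes, immune ligands, cell cycle, metabolism, stress, and markers of 12 other cell types that the sort could hold. Principal components were computed from log2 CPM of the 500 most variable genes.

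Genes named in the text follow a rule. For the fractions within a treatment these were the 10 largest changes in each direction among named genes with an adjusted p under 0.05, at least 10 CPM in the higher group and the same direction in all 6 pairs of libraries that share a number. For control against depleted tumours they were the 8 largest in each direction with every library of a group above every library of the other. For the difference of the changes they were the 5 largest in each direction with at least 10 CPM in 1 group or more. Against the cultures they were the 8 largest with both cultures outside the range of the 12 tumour libraries. To these were added the targets of the sort, up to 4 members of each described list with the smallest p, and 21 genes such as Cdh1, Vim, B2m and Mki67 given whether or not they passed, of which 1 is not reported here. Not every gene that met the rule is named, and a gene picked after its values were seen is marked as such. Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

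Depth sets the precision. Totals of 17559520 to 38740143 counts per library gave 16852 to 20135 detected genes. The median biological coefficient of variation, over 5753 genes, was 8.99% between the cultures and from 12.4% to 13.5% within tumour groups. The lowest chi-square per degree of freedom among 61 pairs of libraries of a group was 13.6, so that no pair agreed within sampling noise and all libraries were kept. PCR reads without molecular identifiers are not independent molecules, and floors of 3 counts for a value of 0 cover counting error only. Counts were simulated from means shared by all groups, with 67 of 16637 genes changed at 1.5-fold, 67 at 2-fold and 66 at 4-fold. The test recovered 65.7%, 79.1% and 98.5% for the fractions of control tumours and 56.7%, 70.1% and 95.5% for those of depleted ones. For the difference of the changes the shares were 35.8%, 70.1% and 86.4% with EpCAM-negative control libraries changed and 32.8%, 59.7% and 92.4% with EpCAM-positive depleted ones. They were 55.2%, 71.6% and 97.0% for control against depleted in EpCAM-positive and 62.7%, 83.6% and 98.5% in EpCAM-negative cells. Against the cultures they were 26.9%, 64.2% and 93.9% for EpCAM-positive and 26.9%, 58.2% and 93.9% for EpCAM-negative cells.

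Both fractions were sorted from each tumour, per the series' design, while the labels do not say that a replicate number names a tumour. Pairing was therefore checked from the deviations of libraries from their group means over 7714 genes with a mean log2 CPM of at least 4. In depleted tumours the correlation of the EpCAM-positive and EpCAM-negative libraries of the same number ran from 0.117 to 0.414, above 0.1 in 6 of 6 pairs, and these numbers were taken to pair the libraries. Alternatives included DESeq2 1.42.0, its size factors in edgeR, limma-voom with sample weights, other filters on low counts, fits of the compared groups alone, a minimum fold, replicate blocks, other EMT scores, other list tests and leaving out libraries. The pathway enrichment named in the series' design was not repeated with outside pathway collections, which were not used here.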

Results

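RNA sequencing was carried out on 26 libraries of E-A14 cells, a mouse mammary tumour line that expresses Her2. The cells had been implanted in the mammary fat pad of FVB/N mice that received either antibodies against CD4 and CD8a, which remove the corresponding T cells, or rat IgG2a and IgG2b as a control. Tumours were taken 20 days after injection from 6 depleted mice and 47 days after injection from 6 control mice. From these tumours Her2-positive cells were sorted into an EpCAM-positive and an EpCAM-negative fraction, after dead cells and cells with CD90, CD105 or CD45 on their surface had been excluded. Each fraction gave 6 libraries per treatment, and the remaining 2 libraries came from the line in culture. Every comparison of control with depleted tumours therefore also compares day 47 with day 20. Total counts per library ran from 17559520 to 25601999 in depleted and from 26895429 to 38740143 in control tumours, so that the depths did not overlap, and the cultures had 27253363 and 35059744. Levels are given as CPM (counts scaled to a common library total) with the SD over the libraries of a group, n = 6 for each tumour group and n = 2 for the cultures. Changes of single genes are log2 fold changes with their standard error, and those called higher or lower had an adjusted p under 0.05.

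The series' design names a principal component analysis. Over the 500 most variable genes, the first component held 60.2% of the variance and the second 23.3%. Control tumours lay at 46.3 ± 4.55 (EpCAM-positive) and 64.1 ± 6.13 (EpCAM-negative) on the first component. Depleted tumours lay at −49.3 ± 2.75 and −40.6 ± 3.46, and the cultures at a mean of −61.3. The second component parted the sorted fractions, with EpCAM-negative cells at 29.3 ± 10.1 (depleted) and 35.0 ± 3.72 (control) and EpCAM-positive cells at −19.1 ± 3.6 and −43.9 ± 4.16. With all 16637 tested genes the first 2 components held 36.6% and 16.9%.

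**Figure D1:**
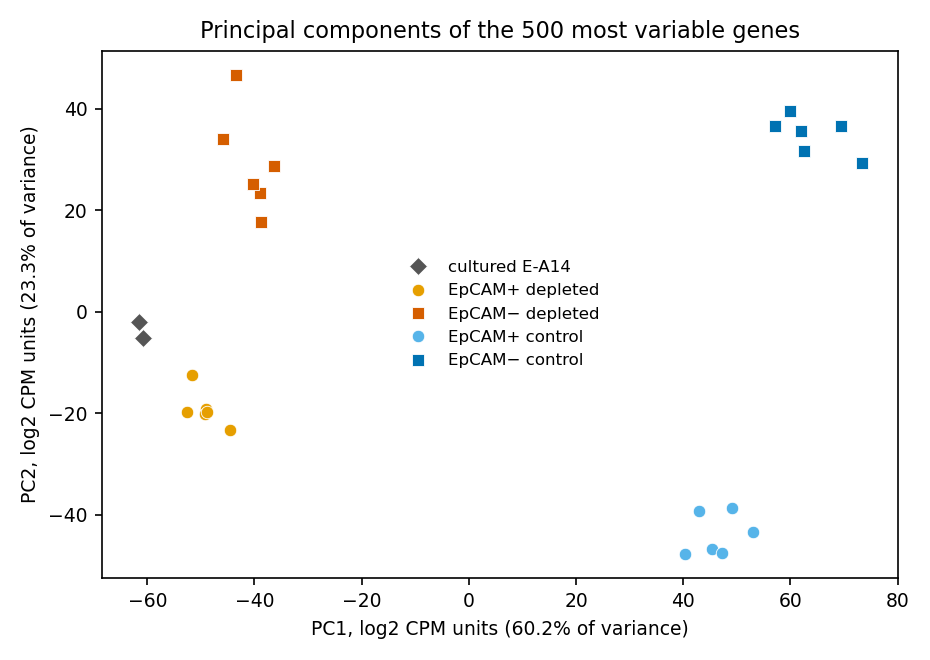
First and second principal component of log2 CPM over the 500 most variable genes, in log2 CPM units, with 1 point per library coloured by group. The 12 control libraries lie to the right of the 12 depleted libraries and the 2 cultures, and the EpCAM-negative libraries lie above the EpCAM-positive ones.

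The targets of the sorting antibodies were examined first. Epcam, the epithelial adhesion molecule used for the gate, averaged 1183 ± 239 CPM in EpCAM-positive and 1.63 ± 0.546 CPM in EpCAM-negative cells of control tumours, a log2 fold change of −9.49 ± 0.40. In depleted tumours the levels were 2437 ± 241 and 140.4 ± 83.4 CPM (log2 fold change −4.12 ± 0.30). The EpCAM-negative fraction thus held 5.76% of the EpCAM-positive level in depleted tumours and 0.138% in control tumours. Over the 6 EpCAM-negative libraries of depleted tumours this share ran from 1.64% to 11.6%. The count table holds the rat Neu transgene as a separate entry, RatActivatedNeu, beside the mouse gene Erbb2, and reads that match both cannot be assigned with certainty. RatActivatedNeu stood at 305 ± 44.2 CPM in EpCAM-positive and 577 ± 66.5 CPM in EpCAM-negative cells of control tumours. It stood at 536 ± 127 and 448 ± 116 CPM in depleted tumours and at 552 ± 50 CPM in the cultures. Erbb2 was lower in the EpCAM-negative cells of both treatments, with log2 fold changes of −1.13 ± 0.09 in control and −1.11 ± 0.09 in depleted tumours. Ptprc, which encodes CD45, averaged 4.43 ± 3.06 and 4.84 ± 2.49 CPM in EpCAM-positive and EpCAM-negative cells of depleted tumours. In those of control tumours it averaged 0.764 ± 0.696 and 0.0567 ± 0.0941 CPM, and the cultures had 0 counts of it. Eng, which encodes CD105, stayed at 3.24 CPM or below in every group mean, and Thy1, which encodes CD90, had at most 5 counts over any group.

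**Figure D2:**
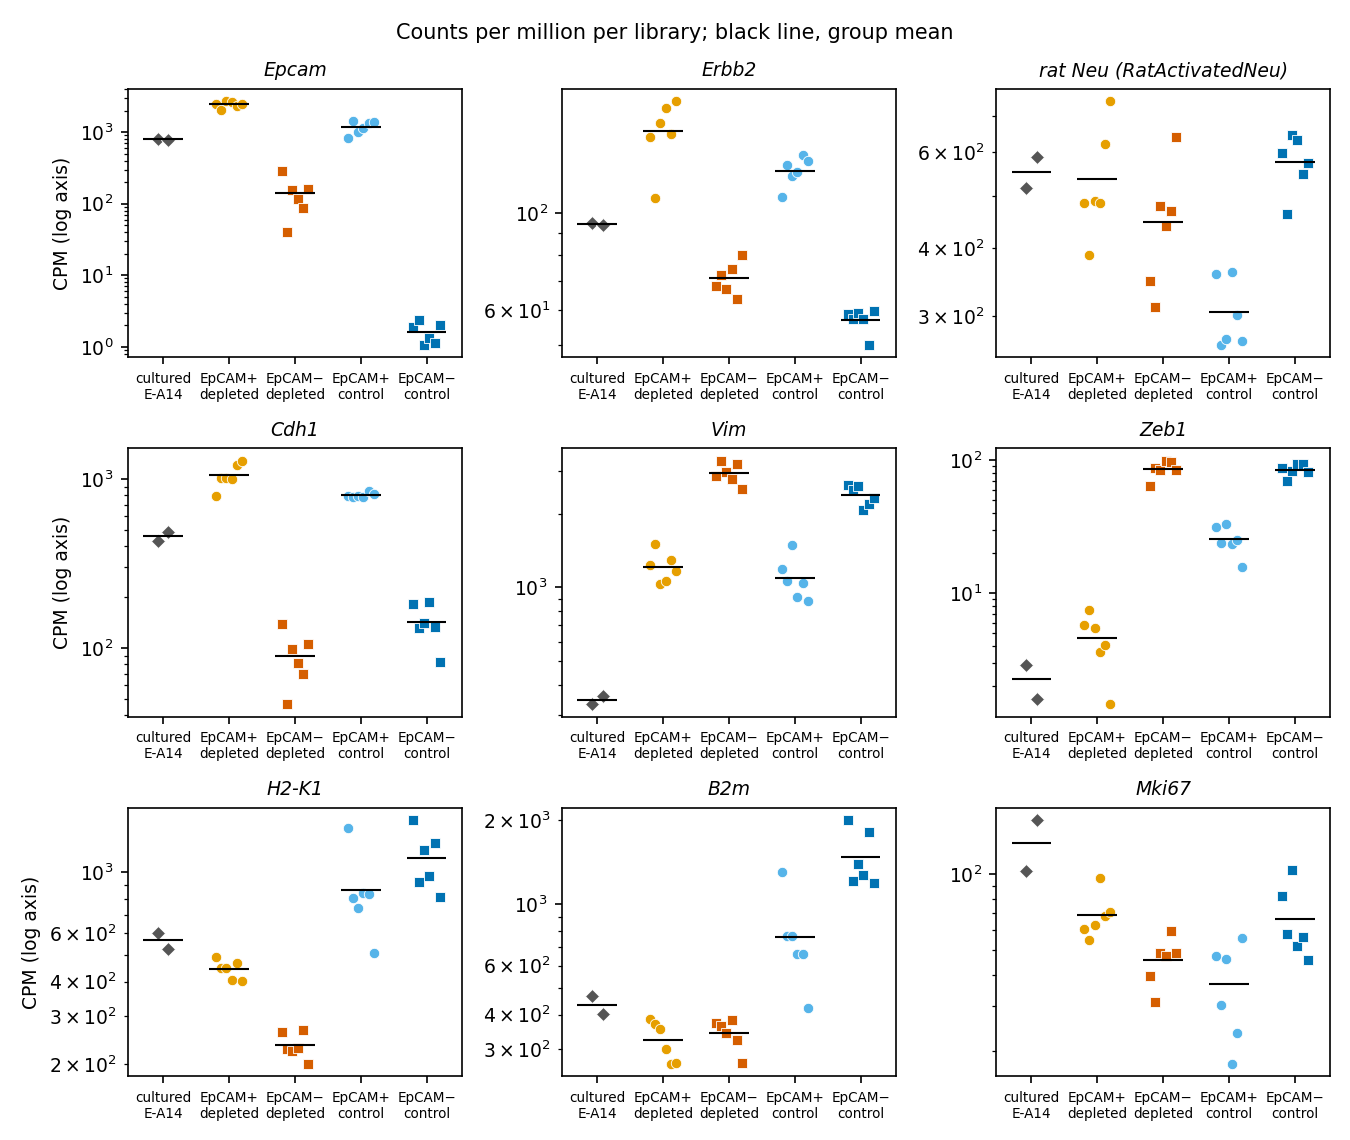
CPM of 9 genes in each library on log axes, by group, with a black line at the group mean. Epcam stands at 2437 and 1183 CPM in the EpCAM-positive means of depleted and control tumours and at 140.4 and 1.63 CPM in the EpCAM-negative means, while B2m and H2-K1 are higher in both control groups than in both depleted groups.

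The design singles out EpCAM-negative against EpCAM-positive cells of control tumours, as mesenchymal against epithelial tumour cells. In the EpCAM-negative cells several epithelial genes were reduced to a few counts. Rab25, a small GTPase of epithelial recycling endosomes, averaged 48.9 ± 10.7 CPM in EpCAM-positive and 0.0194 ± 0.0335 CPM in EpCAM-negative cells (2337-fold lower, counting interval 913 to 8581, or 7582-fold without control library 3, 6 libraries per group). Lsr, a component of tricellular junctions, fell from 53.4 to 0.0569 CPM (934-fold lower, counting interval 522 to 1873, or 2158-fold without control library 6). Spint1, an inhibitor of membrane serine proteases, fell from 54.8 to 0.0544 CPM (953-fold lower, counting interval 532 to 1909, or 1745-fold without control library 1), and the keratin Krt6a from 125 to 0.151 CPM (−9.58 ± 0.51 on the log2 scale, or −10.22 without EpCAM-negative library 2). Genes with up to 3 counts per library in a group are given as ratios with a 95% interval that covers counting error only, and libraries left out are those of the lower group. Pigr, the epithelial immunoglobulin transporter, Hpn, a membrane protease, Sostdc1, a secreted antagonist of BMP and Wnt ligands, and Ggt6 had 16.3, 10.9, 10.4 and 31.5 CPM in EpCAM-positive cells and a single count over the 6 EpCAM-negative libraries each. Pnpla1, a lipase of epidermal ceramide synthesis, had 15.7 ± 4.48 CPM in EpCAM-positive cells and no count in EpCAM-negative cells, where 3 counts per library would give at most 0.104 CPM. Of the epithelial list, 32 of 32 members were lower, 0 higher and 0 did not pass (adjusted p = 3.73e-84, or p = 5.1e-05 with an estimated correlation). Counts of list members rest on the adjustment over all tested genes, and those adjusted over the list alone are added where they differ. Among keratins and desmosomal genes 19 of 21 members were lower, 0 higher and 2 did not pass, or 20 and 0 adjusted over the list alone (adjusted p = 1.78e-36, or p = 9.59e-06 with an estimated correlation). Krt14 changed by −4.31 ± 0.17 and Krt17 by −7.52 ± 0.41. Luminal mammary markers had 14 lower and 1 higher of 21, or 16 and 2 adjusted over the list alone (adjusted p = 2.02e-06, or p = 0.00905 with an estimated correlation). Basal mammary markers had 8 lower and 3 higher of 16, or 10 and 3 adjusted over the list alone (adjusted p = 6.16e-06, or p = 0.00391 with an estimated correlation).

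The mesenchymal list passed in the other direction. In it, 16 of 31 members were higher, 5 lower and 10 did not pass, or 17 and 5 adjusted over the list alone (adjusted p = 9.24e-07, or p = 0.0333 with an estimated correlation). The intermediate filament Vim rose by 1.12 ± 0.11, the membrane metalloprotease Mmp14 by 1.15 ± 0.08, the receptor kinase Axl by 1.20 ± 0.12 and the transcription factor Zeb1 by 1.74 ± 0.21. Snai2, another factor of epithelial-mesenchymal transition (EMT), fell instead (−3.00 ± 0.30). The genes with the highest log2 fold changes included Col6a5, a collagen VI chain (3.84 ± 0.56), the glucose transporter Slc2a3 (3.51 ± 0.67), the cell adhesion gene Pcdh19 (2.85 ± 0.51) and the matrix gene Fbln1 (2.84 ± 0.64). Without EpCAM-positive library 5 the change of Col6a5 was 4.85, and without EpCAM-negative library 5 that of Fbln1 was 2.14. Collagens and matrix genes had 16 higher and 4 lower of 30 (adjusted p = 0.00235, or p = 0.616 with an estimated correlation). Fn1 changed by 1.45 ± 0.16 and Postn by −1.75 ± 0.20. Metalloproteases and their inhibitors had 12 higher and 2 lower of 23, or 13 and 3 adjusted over the list alone (adjusted p = 2.84e-06, or p = 0.0504 with an estimated correlation). Among fibroblast markers, 11 of 18 members were higher, 2 lower and 5 did not pass, or 12 and 2 adjusted over the list alone (adjusted p = 0.00183, or p = 0.455 with an estimated correlation). Pdgfra was one of those higher (1.61 ± 0.16), and the summed CPM of the markers was 11380 ± 1820 against 8666 ± 1660. Of the mitotic G2/M genes, 30 of 30 members were higher, 0 lower and 0 did not pass (adjusted p = 7.04e-14, or p = 0.435 with an estimated correlation). Kif20a, a mitotic kinesin, rose by 1.40 ± 0.18. Replication genes of the G1/S list had 11 higher and 0 lower of 30, or 16 and 1 adjusted over the list alone (adjusted p = 0.000877, or p = 0.711 with an estimated correlation).

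Immune-related genes differed between the fractions as well. Macrophage markers had 14 lower and 1 higher of 21, or 15 and 1 adjusted over the list alone (adjusted p = 0.000751, or p = 0.616 with an estimated correlation). Csf1r, the receptor of macrophage growth factors, changed by −4.13 ± 0.30, and the summed CPM of the markers was 69.3 ± 6.69 in EpCAM-negative and 229.5 ± 63.7 in EpCAM-positive cells. MHC class II genes, which present antigen to CD4 T cells and are made mainly by leukocytes, had 7 lower and 0 higher of 10, or 9 and 0 adjusted over the list alone (adjusted p = 0.02, or p = 0.711 with an estimated correlation). Cd74 changed by −2.96 ± 0.55 and H2-Aa by −2.32 ± 0.53. EpCAM-positive library 1 carries much of this, since without it Cd74 changed by −1.83 (adjusted p = 0.000502) and H2-Aa by −1.31 (adjusted p = 0.0148). The mean log2 CPM of the MHC class II genes was 4.18 in that library and 1.13 to 2.28 in the other 5. The enzyme Arg1, which degrades arginine, changed by −6.03 ± 0.44, and Csf1, a macrophage growth factor, rose from 221 to 399.9 CPM (0.85 ± 0.14). Spp1, the secreted matrix protein osteopontin, took 6.86% of all counts in EpCAM-negative and 3.57% in EpCAM-positive cells (1.08 ± 0.15). Endothelial markers had 8 lower and 1 higher of 18, or 10 and 1 adjusted over the list alone (adjusted p = 0.0256, or p = 0.508 with an estimated correlation), while their summed CPM was 65.2 ± 20.5 against 62.6 ± 23.1 in EpCAM-positive cells. Pericyte and smooth muscle markers had 5 lower and 1 higher of 11 (adjusted p = 0.0379, or p = 0.504 with an estimated correlation). Their summed CPM, 1139 ± 360 against 711.8 ± 163, was mostly Pdgfrb (1064 against 399.2). With the library number as a block the endothelial and pericyte calls were lost (adjusted p = 0.0556 and 0.0926). In total 2233 genes were higher and 2409 lower in EpCAM-negative cells at an adjusted p under 0.05, and of the 4642, 550 were higher and 1304 lower by at least 1 on the log2 scale.

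The same contrast in depleted tumours also parted epithelial from mesenchymal genes. Col5a3, a fibrillar collagen chain, averaged 167 ± 32.3 CPM in EpCAM-negative and 3.56 ± 2.95 CPM in EpCAM-positive cells (5.58 ± 0.60, 6 libraries per group). The water channel Aqp1 rose from 6.73 to 191 CPM (4.82 ± 0.60), and the stromal glycoprotein gene Cd248 from 0.554 to 14.2 CPM (4.75 ± 0.50). Zeb1 rose from 4.61 ± 2.05 to 86.2 ± 12.4 CPM (4.22 ± 0.24) and Zeb2 by 2.73 ± 0.27. Genes that were lower included the lipid flippase Atp8b1 (−4.86 ± 0.47), the membrane protease Tmprss2 (−4.78 ± 0.52), the keratin Krt79 (−4.51 ± 0.50) and the non-muscle myosin Myh14 (−4.16 ± 0.43). Without EpCAM-positive library 2 the change of Cd248 was 5.39, and that of Krt79 was −5.14 without EpCAM-negative library 1 and that of Tmprss2 −5.64 without EpCAM-negative library 3. Cdh1, the E-cadherin gene, fell from 1051 ± 174 to 90.1 ± 31.7 CPM (−3.54 ± 0.20). Of the epithelial list, 28 of 32 members were lower, 0 higher and 4 did not pass, or 29 and 0 adjusted over the list alone (adjusted p = 1.87e-43, or p = 0.000106 with an estimated correlation). Keratins and desmosomal genes had 13 lower and 1 higher of 21, or 14 and 1 adjusted over the list alone (adjusted p = 1.41e-09, or p = 0.0128 with an estimated correlation). Luminal markers had 9 lower and 1 higher of 21, or 10 and 1 adjusted over the list alone (adjusted p = 0.00819, or p = 0.172 with an estimated correlation). Of the mesenchymal list, 15 of 31 members were higher, 4 lower and 12 did not pass (adjusted p = 7.79e-05, or p = 0.123 with an estimated correlation). The integrin subunit Itga5 rose by 1.69 ± 0.12 and Vim by 1.27 ± 0.11. EMT transcription factors had 5 higher and 1 lower of 12 (adjusted p = 0.00622, or p = 0.0393 with an estimated correlation). The TGF-beta list had 16 higher and 4 lower of 28, or 17 and 5 adjusted over the list alone (adjusted p = 0.00622, or p = 0.24 with an estimated correlation), and its member Tgfbi, a matrix gene, rose by 2.74 ± 0.29.

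Groups outside the EMT lists changed too in depleted tumours. Immediate-early genes, which respond within minutes to growth factors and to tissue dissociation, had 23 higher and 0 lower of 29 (adjusted p = 3.51e-12, or p = 0.24 with an estimated correlation). The nuclear receptors Nr4a1 and Nr4a2 rose by 3.50 ± 0.38 and 3.31 ± 0.33 and the phosphatase Dusp5 by 1.75 ± 0.20. Glycolysis genes had 14 higher and 0 lower of 20 (adjusted p = 8.21e-05, or p = 0.298 with an estimated correlation), the enolase Eno2 rising by 1.66 ± 0.20. Hypoxia genes had 11 higher and 1 lower of 19 (adjusted p = 0.00427, or p = 0.37 with an estimated correlation), Bnip3 rising by 1.32 ± 0.18. Mitotic G2/M genes had 12 lower and 0 higher of 30, or 13 and 0 adjusted over the list alone (adjusted p = 0.00622, or p = 0.807 with an estimated correlation). MHC class I presentation had 8 lower and 1 higher of 23, or 8 and 2 adjusted over the list alone (adjusted p = 0.00622, or p = 0.628 with an estimated correlation), and the peptide transporter Tap1 changed by −1.14 ± 0.15. Genes of the multigene H2 family share reads, and FVB/N mice carry another H2 haplotype than the reference mouse, so their levels are uncertain. Macrophage markers summed to 248.7 ± 99.7 CPM in EpCAM-negative and 270.3 ± 45.6 CPM in EpCAM-positive cells. In total 2371 genes were higher and 2378 lower, and of the 4749, 745 were higher and 1007 lower by at least 1 on the log2 scale. With the tumour number as a block, which pairs the libraries of depleted tumours, 4 more lists passed. These were cytokines of myeloid cells (adjusted p = 0.018), NF-kB targets (adjusted p = 0.0279), mitochondrially encoded genes (adjusted p = 0.018) and fibroblast markers (adjusted p = 0.0294). Without the block, their adjusted p with an estimated correlation was 0.37, 0.648, 0.763 and 0.807.

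Of the genes higher in EpCAM-negative cells, 904 were called in both treatments (318 expected from independent lists of these sizes), and of those lower 1019 (344 expected). Another 374 were called in opposite directions, all of which also passed the test of the difference. An EMT score, also named in the design, was formed as the mean log2 CPM of 31 mesenchymal genes minus that of 32 epithelial genes, without Epcam. It was −2.91 in the cultures, −1.70 ± 0.241 in EpCAM-positive and 1.95 ± 0.54 in EpCAM-negative cells of depleted tumours, and −0.71 ± 0.319 and 4.82 ± 0.252 in those of control tumours. The fractions differed by 5.54 in control and by 3.65 in depleted tumours, and control exceeded depleted tumours by 0.99 in EpCAM-positive and 2.88 in EpCAM-negative cells. Each of these 4 differences had p = 0.00216 in an exact two-sided permutation test, the smallest p that its 924 arrangements can give. The difference of the 2 contrasts was 1.89 (exact permutation p = 0.00216). The mean of the epithelial genes was 0.61 in EpCAM-negative cells of control tumours and 3.04 in those of depleted tumours, and that of the mesenchymal genes 5.43 and 4.99. Each EpCAM-negative library of depleted tumours was then reduced by its Epcam share of the EpCAM-positive profile, a step chosen after seeing the data. The difference of the contrasts was then 0.56 (exact permutation p = 0.106), and control exceeded depleted tumours by 1.55 in EpCAM-negative cells (exact permutation p = 0.00216). On the authors' log-scale values, an alternative also chosen after seeing the data, the fractions differed by 3.44 and 2.81 and the treatments by 0.86 and 1.497, each with an exact permutation p of 0.00216. The difference of the contrasts was 0.63 there (exact permutation p = 0.0152).

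**Figure D3:**
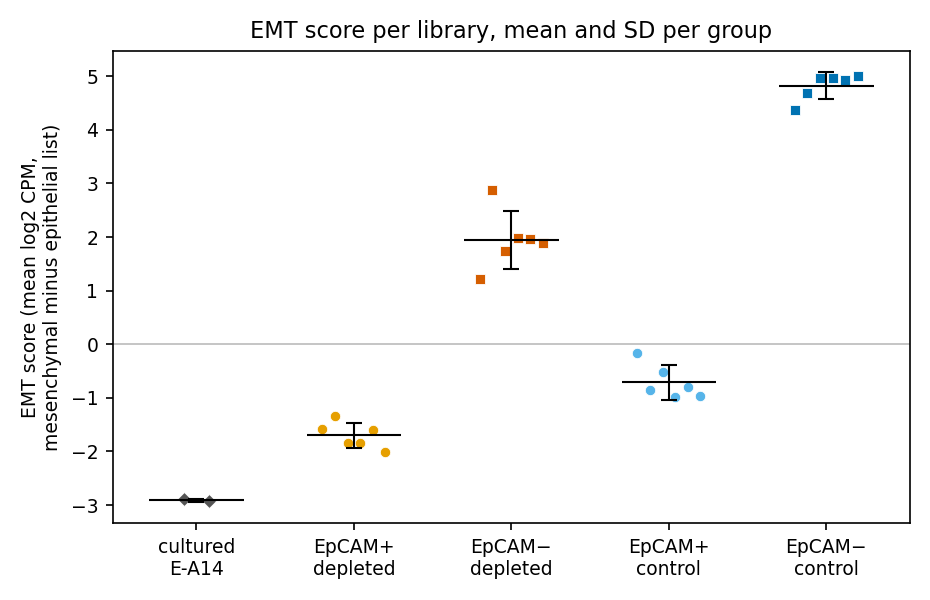
EMT score of each library (mean log2 CPM of the mesenchymal minus the epithelial list), by group, with the group mean as a line and the SD as a bar. The EpCAM-negative libraries of control tumours lie between 4.37 and 5.01, above those of depleted tumours, the highest of which is at 2.89.

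The test of the difference itself called 2996 genes. Of these, 1444 had a more positive and 1552 a more negative EpCAM-negative minus EpCAM-positive change in control than in depleted tumours, and by at least 1 on the log2 scale these were 529 and 795. Mmp3, the metalloprotease stromelysin-1, fell from 1270.0 to 194 CPM in depleted and rose from 572 to 2402 CPM in control tumours (difference 4.78 ± 0.36). Krt6a had the opposite course, at 3.79 and 1.56 CPM in depleted and 125 and 0.151 CPM in control tumours (difference −8.27 ± 0.65, or −8.91 without EpCAM-negative control library 2). Zeb1 averaged 84.8 ± 9.14 and 86.2 ± 12.4 CPM in the EpCAM-negative cells of control and depleted tumours and 25.4 ± 6.24 and 4.61 ± 2.05 CPM in the EpCAM-positive cells (difference −2.49 ± 0.31). RatActivatedNeu differed by 1.18 ± 0.21. Epithelial genes had 20 lower and 1 higher of 32, or 22 and 3 adjusted over the list alone (adjusted p = 1.31e-15, or p = 0.109 with an estimated correlation). Keratins and desmosomal genes had 14 lower and 1 higher of 21, or 14 and 2 adjusted over the list alone (adjusted p = 8.88e-12, or p = 0.0127 with an estimated correlation). Basal markers had 8 lower and 3 higher of 16, or 9 and 4 adjusted over the list alone (adjusted p = 0.00453, or p = 0.109 with an estimated correlation). EMT transcription factors had 4 lower and 0 higher of 12 (adjusted p = 0.0275, or p = 0.109 with an estimated correlation), and their member Snai2 differed by −3.07 ± 0.41. With the tumour number as a block, the calls of basal markers and of EMT transcription factors were lost (adjusted p = 0.0691 for each). TGF-beta genes had 8 lower and 2 higher of 28, or 9 and 5 adjusted over the list alone (adjusted p = 0.0331, or p = 0.315 with an estimated correlation). Metalloproteases and their inhibitors had 8 higher and 4 lower of 23, or 10 and 4 adjusted over the list alone (adjusted p = 8.04e-05, or p = 0.109 with an estimated correlation), and Mmp14 differed by 1.44 ± 0.11. The share of Epcam left in the EpCAM-negative fraction, 5.76% in depleted and 0.138% in control tumours, moved with the epithelial and keratin lists.

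The cell cycle lists differed in the same test. G2/M genes had 25 higher and 0 lower of 30, or 28 and 0 adjusted over the list alone (adjusted p = 1.11e-23, or p = 0.109 with an estimated correlation), and Kif20a differed by 2.09 ± 0.25. G1/S genes had 12 higher and 0 lower of 30, or 14 and 0 adjusted over the list alone (adjusted p = 4.53e-07, or p = 0.285 with an estimated correlation). Immediate-early genes had 20 lower and 0 higher of 29, or 25 and 0 adjusted over the list alone (adjusted p = 1.82e-11, or p = 0.176 with an estimated correlation). MHC class I presentation had 9 higher and 0 lower of 23, or 12 and 0 adjusted over the list alone (adjusted p = 7.98e-07, or p = 0.176 with an estimated correlation), and H2-K1 differed by 1.30 ± 0.24. The antiviral interferon response had 8 higher and 0 lower of 34, or 10 and 2 adjusted over the list alone (adjusted p = 0.00404, or p = 0.233 with an estimated correlation). Its member Usp18, a protease that removes Isg15, differed by 2.06 ± 0.32. MHC class II genes had 6 lower and 0 higher of 10 (adjusted p = 0.0275, or p = 0.571 with an estimated correlation). Macrophage markers had 10 lower and 0 higher of 21, or 11 and 0 adjusted over the list alone (adjusted p = 0.000573, or p = 0.402 with an estimated correlation). Cytokines of myeloid cells had 11 lower and 2 higher of 26, or 13 and 3 adjusted over the list alone (adjusted p = 0.00147, or p = 0.109 with an estimated correlation). NF-kB targets had 6 lower and 1 higher of 26, or 6 and 2 adjusted over the list alone (adjusted p = 0.0482, or p = 0.454 with an estimated correlation) and hypoxia genes 9 lower and 0 higher of 19, or 11 and 2 adjusted over the list alone (adjusted p = 6.76e-05, or p = 0.176 with an estimated correlation). The adenosine pathway had 5 higher and 2 lower of 15, or 5 and 4 adjusted over the list alone (adjusted p = 0.0275, or p = 0.109 with an estimated correlation). Its test and its median change of 0.11 were positive and its mean change of −0.49 was negative. With the tumour number as a block its call was lost (adjusted p = 0.0608). The other passing lists were glycolysis, oxidative phosphorylation, mitochondrially encoded genes, pericyte and endothelial markers (adjusted p 0.00136 to 0.0162, or 0.176 to 0.627 with an estimated correlation). The pericyte test was negative, against the summed CPM (mostly Pdgfrb in control, as above, 39.1 ± 9.59 against 157.3 ± 34.5 in depleted tumours).

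Next, control and depleted tumours were compared within the EpCAM-positive cells. Dcn, the matrix proteoglycan decorin, averaged 1899 ± 583 CPM in control and 1.95 ± 2.06 CPM in depleted tumours (9.98 ± 0.53, 6 libraries per group). Igfbp5, which binds insulin-like growth factors, averaged 1593 ± 582 and 0.689 ± 1.01 CPM (11.27 ± 0.74). Wfdc5 (59.5 ± 28.9 CPM), Pdlim3 (37.7 ± 17.8 CPM) and Scrg1 (29.6 ± 12.4 CPM) had no count in EpCAM-positive cells of depleted tumours. Set against 3 counts per library they were at least 356-fold, 226-fold and 177-fold higher in control tumours. The gelatinase Mmp9 was lower in control tumours, at 0.417 ± 0.498 against 202 ± 67.5 CPM (−8.95 ± 0.51). Also lower were the kallikrein Klk6 (−7.76 ± 0.54), the growth factor Bmp7 (−5.66 ± 0.30) and, of multigene families and hence uncertain, Ly6c2 (−7.24 ± 0.34), Mcpt8 (−6.55 ± 0.74) and Klra4 (−5.27 ± 0.44). Leaving out 1 library moved some of these folds, which came to 10.71 for Dcn without depleted library 2, 12.26 for Igfbp5 without depleted library 6, −9.69 for Mmp9 without control library 5 and −8.47 for Klk6 without control library 2. In total 3725 genes were higher and 2935 lower in control tumours, and of the 6660, 1869 were higher and 820 lower by at least 1 on the log2 scale.

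Interferon-response lists passed as higher in EpCAM-positive cells of control tumours. The antiviral list had 24 higher and 1 lower of 34, or 27 and 1 adjusted over the list alone (adjusted p = 2.03e-11, or p = 0.0113 with an estimated correlation). Rtp4 rose by 4.80 ± 0.31. The gamma-associated list had 19 higher and 2 lower of 23, or 20 and 2 adjusted over the list alone (adjusted p = 4.47e-11, or p = 0.137 with an estimated correlation), and its member Iigp1, an interferon-induced GTPase, had 15 counts over the depleted and 14613 over the control libraries (624-fold higher, counting interval 378 to 1115, or 1130.0-fold without depleted library 6). MHC class I presentation had 19 higher and 3 lower of 23 (adjusted p = 1.43e-05, or p = 0.241 with an estimated correlation), the immunoproteasome subunit Psmb8 rising by 2.81 ± 0.20. NF-kB targets had 15 higher and 1 lower of 26 (adjusted p = 0.00244, or p = 0.241 with an estimated correlation). Immediate-early genes had 23 higher and 1 lower of 29 (adjusted p = 3.48e-09, or p = 0.241 with an estimated correlation), Socs3 rising by 1.90 ± 0.16. Neutrophil markers had 5 lower and 1 higher of 13, or 6 and 1 adjusted over the list alone (adjusted p = 0.0332, or p = 0.169 with an estimated correlation), with summed CPM of 154.6 ± 17.6 and 296.4 ± 77.7. Macrophage markers had 11 lower and 1 higher of 21 (adjusted p = 0.00244, or p = 0.415 with an estimated correlation), with summed CPM of 229.5 ± 63.7 in control and 270.3 ± 45.6 in depleted tumours. T cell markers summed to 6.42 ± 3.74 and 0.854 ± 0.408 CPM. In control tumours Cd28 and Trac, picked out after their values were seen, made up 3.72 and 1.32 CPM of this sum, while Cd3e had 4 counts over the group. Erythroid and platelet markers had 4 lower and 1 higher of 7 (adjusted p = 0.00412, or p = 0.169 with an estimated correlation).

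Matrix, basal and cell cycle lists passed in the same comparison. Collagens and matrix genes had 18 higher and 2 lower of 30 (adjusted p = 1.79e-07, or p = 0.169 with an estimated correlation). Postn, a matrix protein, stood at 2087 ± 421 against 15.6 ± 6.04 CPM (7.06 ± 0.26). Fibroblast markers had 10 higher and 2 lower of 18, or 11 and 2 adjusted over the list alone (adjusted p = 4.43e-06, or p = 0.169 with an estimated correlation), the receptor Pdgfrb rising by 8.15 ± 0.31. Col1a2 and Col3a1, among the most abundant transcripts of fibroblasts and picked out after their values were seen, did not pass, at 38.7 ± 23.1 against 29.7 ± 10.8 and 46.1 ± 18.3 against 49.3 ± 24.1 CPM. Of the 18 tested fibroblast markers, 11 also stand in another list. Pericyte markers had 7 higher and 2 lower of 11 (adjusted p = 0.00244, or p = 0.169 with an estimated correlation) and endothelial markers 9 higher and 1 lower of 18 (adjusted p = 0.0487, or p = 0.399 with an estimated correlation). Basal mammary markers had 14 higher and 1 lower of 16 (adjusted p = 1.79e-07, or p = 0.00307 with an estimated correlation). Among these the transcription factor Trp63 rose by 2.39 ± 0.18 and Krt17 by 3.19 ± 0.31. Epithelial genes had 16 lower and 3 higher of 32 (adjusted p = 0.00209, or p = 0.401 with an estimated correlation). Krt18 changed by −1.68 ± 0.12 and Krt8 by −1.16 ± 0.12. EMT transcription factors had 6 higher and 0 lower of 12 (adjusted p = 0.0251, or p = 0.137 with an estimated correlation) and TGF-beta genes 13 higher and 4 lower of 28 (adjusted p = 0.00231, or p = 0.169 with an estimated correlation). Of the G2/M genes 26 of 30 members were lower, 0 higher and 4 did not pass (adjusted p = 7.91e-12, or p = 0.241 with an estimated correlation), and Kif20a changed by −1.55 ± 0.18. G1/S genes had 16 lower and 0 higher of 30, or 18 and 0 adjusted over the list alone (adjusted p = 0.000146, or p = 0.401 with an estimated correlation). Ribosomal protein genes had 18 lower and 0 higher of 32, or 21 and 0 adjusted over the list alone (adjusted p = 2.39e-05, or p = 0.399 with an estimated correlation).

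In EpCAM-negative cells the treatments differed by 7488 genes, 3859 higher and 3629 lower in control tumours, and 1794 and 1404 by at least 1 on the log2 scale. Btla, an inhibitory receptor otherwise known from lymphocytes, averaged 161 ± 56.2 CPM in control and 0.105 ± 0.0858 CPM in depleted tumours (1542-fold higher, counting interval 902 to 2897, 6 libraries per group), with 154 ± 35.3 and 1.36 ± 0.992 CPM in the EpCAM-positive cells. Adamtsl2, a regulator of matrix assembly, had 31.6 ± 34.4 CPM in control and no count in depleted tumours. The same held for Fam180a (17.6 ± 16.6 CPM), Scrg1 (13.9 ± 10.8 CPM) and the hyaluronan-binding gene Hapln2 (11.5 ± 6.28 CPM). Set against 3 counts per library these were at least 111-fold (Fam180a), 88.1-fold (Scrg1) and 72.6-fold (Hapln2) higher. Bmp7 was lower in control tumours, at 0.302 ± 0.346 against 221 ± 36 CPM (log2 fold change −9.41 ± 0.38). Klk6 (823-fold lower, counting interval 447 to 1718), the cytokine Il24 (357-fold lower, counting interval 173 to 889, or 709-fold without control library 5), the integrin subunit Itgb7 (316-fold lower, counting interval 176 to 633, or 563-fold without control library 3) and the serotonin transporter Slc6a4 (log2 fold change −7.57 ± 0.91) were lower as well. The fold of Slc6a4 rests on control library 6, without which it was −10.84. That of Bmp7 was −10.26 without control library 2. Serpinb2, an inhibitor of plasminogen activators, had 21.7 ± 7.32 CPM in depleted and no count in control tumours, at least 208-fold lower.

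The interferon lists passed as higher in this fraction too. The antiviral list had 28 higher and 1 lower of 34, or 29 and 2 adjusted over the list alone (adjusted p = 2.96e-15, or p = 0.0097 with an estimated correlation). Rtp4 rose by 6.07 ± 0.33, Ifit3 by 5.36 ± 0.37 and Usp18 by 3.66 ± 0.24. The gamma-associated list had 19 higher and 2 lower of 23 (adjusted p = 4.16e-09, or p = 0.0805 with an estimated correlation). MHC class I presentation had 21 higher and 1 lower of 23 (adjusted p = 1.16e-14, or p = 0.0507 with an estimated correlation). H2-K1 stood at 1125 ± 274 against 234 ± 25.2 CPM (2.26 ± 0.17), and Psmb8 rose by 3.12 ± 0.21. Macrophage markers had 17 lower and 0 higher of 21, or 19 and 1 adjusted over the list alone (adjusted p = 1.05e-06, or p = 0.266 with an estimated correlation) and summed to 69.3 ± 6.69 CPM in control and 248.7 ± 99.7 CPM in depleted tumours. Lyz2 changed by −4.70 ± 0.57, and the chemokine receptor Ccr2 had 2 counts over the control and 428 over the depleted libraries (327-fold lower, counting interval 90 to 2711, or 545-fold without control library 1, or 557-fold without control library 4). T cell markers summed to 11.9 ± 4.21 and 2.32 ± 0.41 CPM. In control tumours Cd28 and Trac made up 8.56 and 3.03 CPM of this sum, while Cd3e had 1 count over the group. Cd4 had no count in control tumours, and 11 and 7 counts over the EpCAM-positive and EpCAM-negative fractions of depleted ones. Neutrophil markers had 8 lower and 1 higher of 13 (adjusted p = 0.0265, or p = 0.145 with an estimated correlation), but a higher summed CPM, at 250.6 ± 48.3 against 136.1 ± 37.9. Erythroid and platelet markers had 6 lower and 0 higher of 7 (adjusted p = 0.00132, or p = 0.0644 with an estimated correlation). Adenosine pathway genes had 7 higher and 4 lower of 15 (adjusted p = 0.00293, or p = 0.0354 with an estimated correlation). The ectoenzymes Enpp1, Alpl and Cd38 rose by 2.70 ± 0.15, 7.77 ± 0.28 and 1.84 ± 0.17.

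In the same fraction, collagens and matrix genes had 19 higher and 1 lower of 30 (adjusted p = 6.74e-09, or p = 0.086 with an estimated correlation), with Col8a1 rising by 6.00 ± 0.28. Fibroblast markers had 12 higher and 0 lower of 18 (adjusted p = 5.63e-09, or p = 0.0507 with an estimated correlation). Of the abundant fibroblast collagens, Col1a2 stood at 13.4 ± 9.39 CPM in control and 19.6 ± 6.73 CPM in depleted tumours and did not pass. Metalloproteases and their inhibitors had 12 higher and 6 lower of 23, or 13 and 6 adjusted over the list alone (adjusted p = 8.01e-05, or p = 0.086 with an estimated correlation), Mmp14 rising by 1.80 ± 0.08. Epithelial genes had 23 lower and 3 higher of 32, or 25 and 3 adjusted over the list alone (adjusted p = 2.13e-14, or p = 0.0805 with an estimated correlation). Keratins and desmosomal genes had 14 lower and 2 higher of 21, or 15 and 2 adjusted over the list alone (adjusted p = 1.8e-06, or p = 0.0507 with an estimated correlation), with Epcam at 0.138% of its EpCAM-positive level in control and 5.76% in depleted tumours. Glycolysis genes had 11 lower and 2 higher of 20 (adjusted p = 0.00762, or p = 0.515 with an estimated correlation), the hexokinase Hk2 changing by −2.03 ± 0.22. Ribosomal protein genes had 16 lower and 0 higher of 32 (adjusted p = 0.00614, or p = 0.721 with an estimated correlation). Between treatments, 2375 genes were higher in both fractions (864 expected from independent lists), 1735 lower in both (640.2 expected) and 319 opposite. Fractions of the same tumours are not independent. Of the gene lists, 5 passed as higher and 5 as lower in both fractions, while with an estimated correlation 2 lists were called in each fraction.

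**Figure D4:**
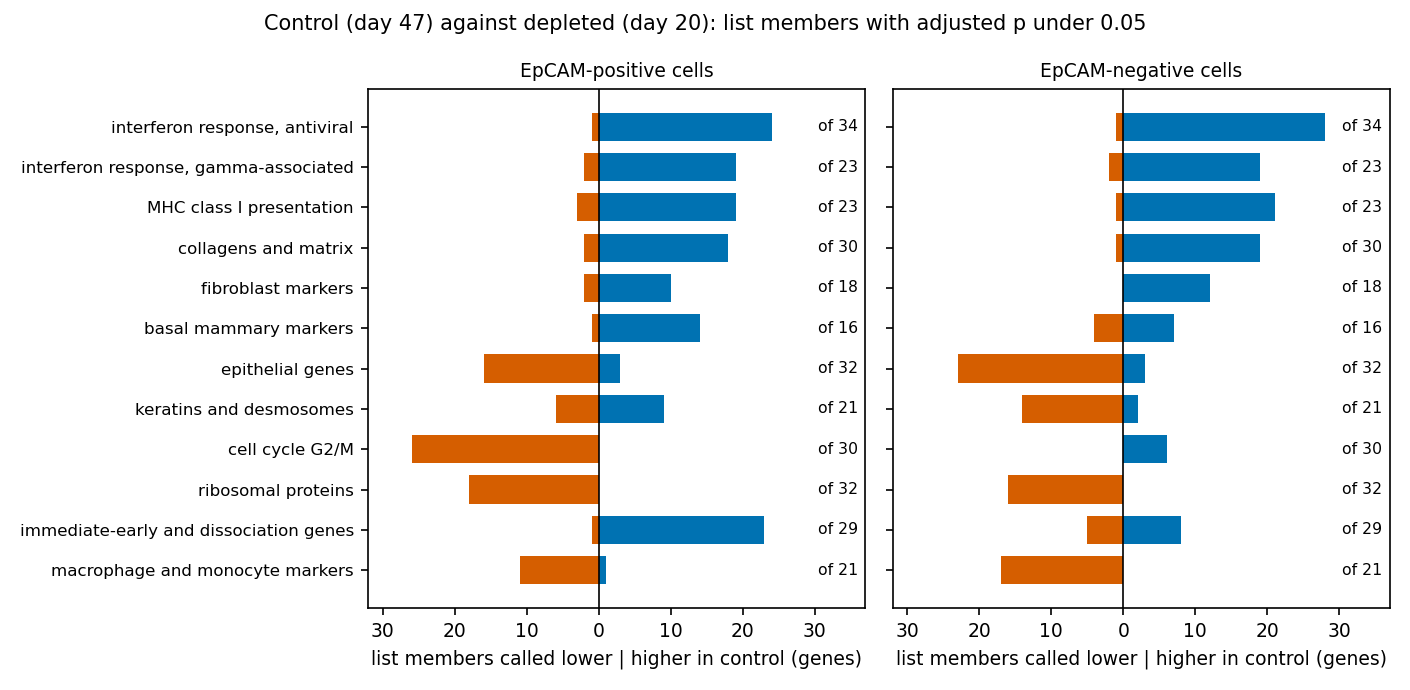
Number of members of 12 gene lists called higher (blue, to the right) or lower (orange, to the left) in control than in depleted tumours, in EpCAM-positive and EpCAM-negative cells, with the number of tested members at the right. In the antiviral interferon list 24 and 28 of 34 members are higher, and of the 30 G2/M genes 26 are lower in EpCAM-positive and 6 higher in EpCAM-negative cells.

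Further genes chosen in advance were compared across the 4 tumour groups. Cdh1, unlike most of the epithelial list, was higher in EpCAM-negative cells of control than of depleted tumours, at 142 ± 38.3 against 90.1 ± 31.7 CPM (0.66 ± 0.19). Snai1, a repressor of Cdh1, stood at 16.8 ± 2.95 and 35.8 ± 5.55 CPM in EpCAM-positive and EpCAM-negative cells of control tumours and at 9.78 ± 1.39 and 19.6 ± 3.42 CPM in those of depleted tumours. It passed the test between fractions in both treatments and between treatments in both fractions. Twist1, at 0.462 CPM or below in every group mean, did not pass between the fractions. B2m, the light chain of MHC class I, was higher in control tumours in EpCAM-positive (1.24 ± 0.18) and EpCAM-negative cells (2.11 ± 0.19), as was H2-D1 (0.93 ± 0.18 and 1.77 ± 0.18). Cd274, which encodes PD-L1, stood at 1.5 CPM or below in each group mean and passed none of the 7 tests. Nt5e, which encodes the ectoenzyme CD73, averaged 779.7 ± 57.4 and 958 ± 140.0 CPM in the fractions of control and 1565 ± 137 and 1434 ± 163 CPM in those of depleted tumours, lower in control in both. The interferon-induced chemokine gene Cxcl9 had 85 and 84 counts over the 6 EpCAM-positive and 6 EpCAM-negative control libraries and none in depleted tumours. Cxcl10 averaged 2.18 ± 0.831 CPM in EpCAM-negative cells of control and 0.0647 ± 0.121 CPM in those of depleted tumours. Ccl5, another chemokine gene, lay at 0.246 CPM or below in every tumour group and at 2.35 ± 0.534 CPM in the cultures. Ccl2 averaged 1.17 ± 0.816 and 1.62 ± 1.08 CPM in EpCAM-positive and EpCAM-negative cells of depleted tumours. In those of control tumours it averaged 1.96 ± 4.14 and 4.72 ± 10.1 CPM, where library 3 alone had 10.4 and 25.4 CPM, and it passed no test between tumour groups. Mki67, a marker of cycling cells, was higher in the EpCAM-negative than the EpCAM-positive cells of control tumours (0.85 ± 0.24), at 66.3 ± 22.2 against 36.9 ± 15.2 CPM. In depleted tumours, at 45.9 ± 9.62 against 69 ± 14.6 CPM, it did not pass, and the difference of the changes was 1.43 ± 0.34.

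Finally, the tumour cells were compared with the cultured line, each fraction taken as the mean of its control and depleted groups. The matrix gene Sparc was higher in tumour cells by 5.55 ± 0.22 (EpCAM-positive) and 6.11 ± 0.23 (EpCAM-negative) on the log2 scale (12 libraries against 2 cultures), and Trp63 by 8.21 ± 0.44 and 8.02 ± 0.44. The chemokine Cxcl14 had 1 count over both cultures and 54 ± 16.4 CPM in EpCAM-positive cells of depleted tumours. Sncg, which encodes gamma-synuclein, and Cables1, a regulator of cyclin-dependent kinases, had no count in the cultures. In EpCAM-positive cells of control tumours they averaged 25.4 ± 5.97 and 44.3 ± 14.5 CPM, at least 264-fold and 461-fold higher. The cystine transporter Slc7a11 stood at 55.1 ± 5.32 CPM in culture against 0.567 ± 0.594 CPM in EpCAM-positive cells of depleted tumours (−7.22 ± 0.74 for the mean of the EpCAM-positive groups), and Cth, which makes cysteine from cystathionine, changed by −6.74 ± 0.57. The calcium-binding S100a7a was also higher in culture (−6.34 ± 0.31). So were Wnt7a, at 68 ± 0.101 against 1.27 ± 0.542 (depleted) and 0.0493 ± 0.121 CPM (control, all 9 counts in library 2) in EpCAM-positive cells, and the alcohol dehydrogenase Adh7, at 63.8 ± 3.53 against 0.0172 ± 0.0267 and 0.864 ± 0.567 CPM. Without EpCAM-positive control library 1 the change of Slc7a11 was −8.18. In EpCAM-positive tumour cells 4050 genes were higher and 3535 lower than in culture, and of these 7585 genes 2402 and 1443 by at least 1 on the log2 scale. In EpCAM-negative cells the numbers were 4031 and 3860, and of these 7891 genes 2367 and 1744.

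Cell cycle lists passed as lower in tumour cells of both fractions than in culture. Of the G2/M genes in EpCAM-positive cells 30 of 30 members were lower, 0 higher and 0 did not pass (adjusted p = 2.6e-26, or p = 0.0905 with an estimated correlation). In EpCAM-negative cells they had 30 lower and 0 higher of 30 (adjusted p = 6.3e-18, or p = 0.121 with an estimated correlation), and Top2a changed by −2.98 ± 0.19 and −2.61 ± 0.19. G1/S genes had 29 lower and 0 higher of 30 (adjusted p = 6.23e-20, or p = 0.0621 with an estimated correlation) in EpCAM-positive cells, with Mcm2 changing by −2.01 ± 0.14. In EpCAM-negative cells the list had 28 lower and 0 higher of 30 (adjusted p = 3e-16, or p = 0.0767 with an estimated correlation). Collagens and matrix genes had 26 higher and 2 lower of 30, or 27 and 2 adjusted over the list alone (adjusted p = 2.26e-13, or p = 0.0544 with an estimated correlation) in EpCAM-positive cells. Their counts in EpCAM-negative cells were 25 higher and 3 lower of 30 (adjusted p = 2.94e-14, or p = 0.0362 with an estimated correlation). Immediate-early genes had 23 higher and 2 lower of 29, or 24 and 3 adjusted over the list alone (adjusted p = 5.12e-11, or p = 0.156 with an estimated correlation) in EpCAM-positive and 24 higher and 2 lower of 29, or 25 and 2 adjusted over the list alone (adjusted p = 3.95e-15, or p = 0.0963 with an estimated correlation) in EpCAM-negative cells. Their member Jun rose by 3.73 ± 0.22 and 3.67 ± 0.22. The labels give the digestion and the sort for the tumours, and a cell suspension without sorting for the cultures.

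Among immune-related lists, MHC class I presentation had 18 higher and 0 lower of 23 (adjusted p = 8.92e-10, or p = 0.0905 with an estimated correlation) in EpCAM-positive tumour cells. The peptide-loading factor Tapbp rose by 1.90 ± 0.10. Complement genes had 16 higher and 0 lower of 20, or 17 and 0 adjusted over the list alone (adjusted p = 0.000223, or p = 0.151 with an estimated correlation). Immune checkpoints and ligands had 15 higher and 3 lower of 25, or 17 and 4 adjusted over the list alone (adjusted p = 0.000515, or p = 0.0544 with an estimated correlation). Macrophage markers, at 70.9 ± 1.14 summed CPM in the cultures, had 20 higher and 1 lower of 21 (adjusted p = 0.000119, or p = 0.304 with an estimated correlation). MHC class II genes had 7 higher and 0 lower of 10, or 8 and 0 adjusted over the list alone (adjusted p = 0.0213, or p = 0.478 with an estimated correlation). TGF-beta genes had 18 higher and 2 lower of 28, or 19 and 2 adjusted over the list alone (adjusted p = 3.27e-06, or p = 0.0544 with an estimated correlation) and basal markers 14 higher and 1 lower of 16 (adjusted p = 5.9e-09, or p = 0.000465 with an estimated correlation). In EpCAM-negative cells the epithelial genes had 28 lower and 0 higher of 32 (adjusted p = 2.86e-32, or p = 0.00705 with an estimated correlation). In all, 17 lists passed as higher and 4 as lower in EpCAM-positive cells, and 16 and 4 in EpCAM-negative cells. With an estimated correlation 1 and 5 of these lists were still called. Both comparisons use the same 2 cultures, which also limit their precision.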

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

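Of the tests in this part, those for fibroblasts and for EpCAM-positive cells in the EpCAM-negative sort, the removal of the Epcam share and the refits without depleted tumour 2 were chosen only after the result was seen, and the fibroblast test was divided by fraction after its values were known.

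Over 12 measures in the 4 tumour groups, 4 of 48 groups of 6 libraries held a library that stood far from the others by Dixon's test at the 95% level. Chance marks about 1 in 20 groups. EpCAM-negative library 2 of depleted tumours had 16852 genes detected, against 18021 to 18411 in the others of its group. EpCAM-positive library 2 of depleted tumours lay at −12.4 on the second principal component, the others between −23.3 and −19.3. Without both libraries of that tumour the counts of changed genes that involve depleted tumours ran from 2985 for the difference of the EpCAM changes to 8020 for EpCAM-negative cells against the cultures. EpCAM-negative library 5 of control tumours had 50.1 CPM of Erbb2, against 57.2 to 59.9 CPM. EpCAM-negative library 1 of control tumours had a macrophage marker sum of 81.6 CPM, against 63.1 to 69.8 CPM.

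The change between EpCAM-negative and EpCAM-positive cells differed between control and depleted tumours in 4 tested results. It differed for 2996 genes and 22 gene lists (1 of them with an estimated correlation), for the EMT score by 1.89 (4.52 to 5.97 over the 6 control and 2.80 to 4.22 over the 6 depleted pairs of libraries that share a number) and for RatActivatedNeu by 1.18 on the log2 scale. Counts of changed genes were compared over 100 of 462 divisions, in fits of the compared libraries alone. Only the real one called as many in each of 5 comparisons (1 in 100, the floor). Mixed divisions put unlike groups on both sides, which lowers their counts. The real division called 4322 genes between the fractions of control tumours (highest other 13), 4517 between those of depleted tumours (31) and 2947 for the difference (1). It called 6370 between treatments in EpCAM-positive cells (109) and 7226 in EpCAM-negative cells (486). Among the 32 divisions of the depleted libraries that part all pairs, the highest other called 1 gene.

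The EpCAM-negative cells of depleted tumours kept 5.76% of the Epcam level of the EpCAM-positive cells, against 0.138% in control tumours, and their EMT score lay lower. EpCAM-positive cells in the EpCAM-negative sort may account for part of this, since 22 genes left at under 1% in control tumours were left at a median of 8.12% in depleted tumours (quartiles 7.16% and 8.78%) and followed Epcam over the 6 libraries with a median r of 0.947 across those genes, which are not independent. Removing each library's Epcam share of the EpCAM-positive profile left a difference of the EMT contrasts of 0.557 (exact permutation p = 0.106, from 1.89 before), as the contrast of depleted tumours went from 3.65 ± 0.478 to 4.98 ± 0.51 (SD), while the count of genes with a different EpCAM change was 3117. Of 7129 genes with at least 20 CPM in EpCAM-positive cells none was left below 3.54% in depleted tumours, whereas by the same minimum 31 genes were left under 1% in control tumours. Cells with partial EpCAM expression at the gate, and a difference between the treatments or days themselves, stay open and were not tested.

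In cells sorted without CD90 and CD105, fibroblast markers had 10 higher and 2 lower of 18 in EpCAM-positive and 12 higher and 0 lower in EpCAM-negative cells of control tumours (adjusted p = 4.43e-06 and 5.63e-09, lost with an estimated correlation at p = 0.169 and 0.0507). In EpCAM-positive cells Col1a1, Lum and Dcn were called higher and RatActivatedNeu was lower (−0.81 ± 0.15), as fibroblasts would give, but 2 of 5 abundant fibroblast transcripts, Col1a2 (0.38 ± 0.40) and Col3a1 (−0.09 ± 0.40), were not called higher while Dcn rose from 1.95 to 1899 CPM, which argues against fibroblasts as the whole source there. In EpCAM-negative cells 1 of the 5, Col1a2, was not called higher (13.4 against 19.6 CPM), Col1a1 rose from 34.8 to 1544 CPM and RatActivatedNeu was not lower (0.36 ± 0.15, adjusted p = 0.0491, a call lost under 6 of its 10 alternatives). For that fraction, fibroblasts in the sort and expression by the tumour cells cannot be told apart, because a single transcript decides too little. Of the 18 fibroblast markers tested, 7 reached 1 CPM in the cultured line, and a difference between treatments or days stays open as untested.

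Control and depleted tumours differed by 6660 genes in EpCAM-positive and 7488 in EpCAM-negative cells, and their depths did not overlap. Thinning every tumour library to 17559520 counts kept 96.1% and 95.2% of these calls in the same direction, which argues against depth as the cause. A copy number difference between the tumour cells would shift neighbouring genes together, but 0 of 334 windows of 50 genes went beyond the highest of 1000 shuffles in both fractions. That search found a shift of 100 genes in 100% of trials at 1.5-fold but in 21.0% at the smallest change tried, so that short or small changes stay open. Treatment, harvest day and possibly processing batch coincide, and any may lie behind the difference.

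Within groups of tumour libraries the correlation of MHC class II with macrophage genes did not pass, with Pearson's r = 0.483 (permutation p = 0.062) and Spearman's rho = 0.431 (permutation p = 0.061) over 24 libraries, and r = 0.543 without the 2 farthest libraries. Within the groups r was 0.497 and 0.808 in EpCAM-positive and EpCAM-negative cells of depleted tumours and 0.521 and −0.343 in those of control tumours.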

How the results depend on the processing

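Leaving out both libraries of depleted tumour 2, leaving out a culture in the list tests, removing the Epcam share and the EMT score from the authors' log2-like values were chosen after seeing the data. Of 286 alternative values of the counts, scores, list tests and components, 265 kept their direction and their side of the threshold (for counts, stayed within 1.5 times), and none turned its direction. Requiring a log2 fold change of at least 1 lowered the calls by construction, to 1854 and 1752 for the fractions of control and depleted tumours, 1324 for the difference, 2689 and 3198 for the treatments in EpCAM-positive and EpCAM-negative cells, and 3845 and 4111 against the cultures. DESeq2 called 4749, 4995, 3316, 6754, 7616, 7945 and 8182 genes in the same order, and no gene called by both tools had opposite directions in them. Leaving out each library in turn gave 4061 to 4524, 4327 to 4702, 2727 to 3036, 6113 to 6514, 6997 to 7355, 5387 to 7634 and 5664 to 8010 genes. The lowest values against the cultures came without culture 1, which leaves a lone culture that is assumed to vary like the other groups. The EMT differences ran from 5.48 to 5.65 and from 3.46 to 3.79 between the fractions of control and depleted tumours, from 0.88 to 1.06 and from 2.73 to 3.07 between treatments in EpCAM-positive and EpCAM-negative cells, and from 1.72 to 2.09 for the difference of the contrasts. That difference was 0.573 with genes scaled to unit variance and 0.633 on the authors' values (with 1.497 between treatments in EpCAM-negative cells), and with the score without matrix genes the 3 passed their exact permutation tests (p from 0.00433 to 0.0152). A logarithm of the authors' values was not run, since these are on a log scale as deposited. With the Epcam share removed the difference between treatments in EpCAM-negative cells was 1.546. That of the contrasts was 0.557 and no longer passed (exact permutation p = 0.106). The contrast of depleted tumours, which the removal widens by construction, came to 4.98 ± 0.51 (SD), close to the 5.54 ± 0.535 of control tumours. An estimated correlation between genes left 5, 3, 1, 2, 2, 1 and 5 lists called, from 14, 11, 22, 19, 14, 21 and 20, since camera then allows for genes that move together. With fry, which asks whether the genes of a list move on balance and sets them against no other genes, 23, 20, 21, 31, 29, 31 and 32 lists passed. The first principal component held 36.6% of the variance over all tested genes, in place of 60.2%, because genes that vary less are then included. In control tumours libraries sharing a number correlated at 0.056 to 0.43, above 0.1 in 5 of 6 pairs. As in depleted tumours, 5 of 6 correlated best with their own number. Number 6 alone missed the rule, so control pairing stays open. No pair of control and depleted libraries passed 0.1 in either fraction, and none correlated best with its own number. With the tumour number as a replicate block 4947, 5066 and 3310 genes were called for the fractions and their difference, and with the number as a block 5611, 6522, 6150 and 6210 for the other comparisons. The block changed the list calls from 14 to 13 in control tumours (MHC class I gained, pericyte and endothelial markers lost), from 11 to 15 in depleted tumours and from 22 to 19 for the difference (EMT transcription factors, basal markers and the adenosine pathway lost), and left the other list calls of these comparisons as they were. In sign flips of the pairs the EMT differences of 5.54 and 3.65 had an exact p = 0.0312, the smallest that 6 pairs can give. Of 1082 alternative values of single genes named, 1072 kept direction and call and 10 lost the call, 5 of them by construction at a log2 fold change of at least 1 and 5 for RatActivatedNeu between treatments in EpCAM-negative cells. That call (log2 fold change 0.36, adjusted p = 0.0491) also ended without any single EpCAM-negative library but depleted 6 and control 2 (adjusted p from 0.0557 to 0.125), with log2 fold changes from 0.28 to 0.49 over all 12, and the cause was not tested. Without 1 library the fitted fold of a named gene moved by over 1.5 times in 23 of 118 gene changes, and these 23 were still called. In low-count genes depth limits what can be said, so that bounds or ratios with counting intervals are given.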

Other observations

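No test of this part was chosen after its result was seen, but the single genes known from leukocytes were picked out once their levels had been seen.

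Genes otherwise known from leukocytes were expressed in libraries with few or no reads of Ptprc, the gene of the pan-leukocyte antigen CD45. The cultured line, with 0 counts of Ptprc and of Cd3e, a part of the T cell receptor complex, had 28.1 ± 1.82 CPM of Siglecg, a sialic acid receptor of B cells (SD, n = 2). It also had 200.3 ± 12.2 CPM of Klra4, 28.1 ± 1.24 CPM of Klra1 and 11.1 ± 0.277 CPM of Mcpt8. These 3 belong to multigene families, and their short reads cannot be assigned with certainty. In tumour cells Siglecg averaged 1.17 ± 0.94 CPM in EpCAM-negative cells of depleted tumours, and it had 2 counts over each fraction of control tumours. Pilra, a receptor of myeloid cells, averaged 34.4 ± 8.6 CPM in EpCAM-negative and 5.37 ± 1.41 CPM in EpCAM-positive cells of control tumours (n = 6 each), where Ptprc averaged 0.0567 and 0.764 CPM. In depleted tumours Pilra averaged 2.73 ± 1.57 and 1.5 ± 0.772 CPM. Btla had 10 counts over both cultures, and Cd79a, a part of the B cell receptor, had at most 6 counts over any group.

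Lists of the respiratory chain were tested as well. Nuclear genes of oxidative phosphorylation had 3 higher and 0 lower of 30, or 2 and 0 adjusted over the list alone (adjusted p = 0.00734, or p = 0.627 with an estimated correlation) for the difference of the EpCAM changes. Mitochondrially encoded genes had 4 higher and 0 lower of 7, or 6 and 0 adjusted over the list alone (adjusted p = 0.0162, or p = 0.454 with an estimated correlation) in the same test. Against the cultures, oxidative phosphorylation had 9 lower and 0 higher of 30 (adjusted p = 0.0213, or p = 0.623 with an estimated correlation) in EpCAM-positive tumour cells and 0 higher and 11 lower of 30 (adjusted p = 0.0502) in EpCAM-negative ones. Luminal mammary markers, between control and depleted tumours, had 15 higher and 4 lower of 21 (adjusted p = 0.116) in EpCAM-positive and 8 higher and 5 lower of 21, or 8 and 6 adjusted over the list alone (adjusted p = 0.917) in EpCAM-negative cells.

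Of the lists tested, 8 passed the list test in none of the 7 comparisons. Chemokines had 14 higher and 5 lower of 26, or 15 and 5 adjusted over the list alone (adjusted p = 0.109) for EpCAM-positive tumour cells against culture and 6 higher and 8 lower of 26, or 7 and 9 adjusted over the list alone (adjusted p = 0.974) between treatments in EpCAM-negative cells. Heat shock genes had 7 higher and 7 lower of 17 (adjusted p = 0.752) for EpCAM-positive tumour cells against culture. Ligands of NK cell receptors had 3 higher and 5 lower of 11, or 3 and 6 adjusted over the list alone (adjusted p = 0.954) between treatments in EpCAM-negative cells. Between treatments in EpCAM-positive cells T cell markers had 3 higher and 0 lower of 5, or 3 and 1 adjusted over the list alone (adjusted p = 0.297), B cell and plasma cell markers 4 higher and 1 lower of 6 (adjusted p = 0.958) with a lower summed CPM of 1357 ± 135 against 2322 ± 96.7, dendritic cell markers 2 higher and 2 lower of 9 (adjusted p = 0.899) and muscle markers 0 higher and 2 lower of 9 (adjusted p = 0.128). Adipocyte markers had 0 higher and 2 lower of 5, or 1 and 2 adjusted over the list alone (adjusted p = 0.873) between the fractions of control tumours. Of the tested members, 2 of 5 T cell, 1 of 6 B cell, 2 of 9 dendritic cell, 4 of 9 muscle and 1 of 5 adipocyte markers reached 1 CPM in the cultured line. For the lists described earlier the numbers were 2 of 11 pericyte, 3 of 18 endothelial, 3 of 21 macrophage, 3 of 13 neutrophil, 1 of 7 erythroid and 3 of 10 MHC class II genes. The lists also share genes. Of the pericyte, macrophage, neutrophil, MHC class II, dendritic cell, endothelial and muscle genes tested, 6, 6, 3, 3, 1, 1 and 1 stand in another list. The remaining 2 lists had too few tested members for a list test. Of the 4 tested targets of the sort antibodies, 3 were lower and 0 higher between the fractions of control tumours. Of the 3 tested NK cell and cytotoxic markers, 1 was higher and 0 lower in the difference of the EpCAM changes, also when adjusted over the list alone.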
